A study of Mus musculus with 2 samples.

How the data were processed

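Gene expression was measured in 2 single-cell libraries, 1 of young and 1 of aged mouse SVZ cells, with the 10x Genomics 3′ version 3 chemistry, per the labels' protocols. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 3.0.2 against mm10, per the submitters' processing notes, and the file headers give the same software version. The barcodes were already limited to called cells, with at least 500 UMIs each, and no normalization had been applied. The gene annotation used for counting is not given in the sources used here. Of 27998 gene identifiers, 27645 were found in a reference table of gene names, which gave another symbol for 1169 of them. The list members Cebpd, Rian and Trac did not match any symbol in the matrices. Coordinates were taken by gene identifier from GENCODE vM21 on GRCm38, and are 1-based.

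Cells were kept with at least 1000 detected genes and at most 10% of UMIs from the 13 mitochondrially encoded genes. In the young library 951 barcodes had fewer genes and 1550 had more mitochondrial UMIs, and in the aged library 742 and 1452. Scrublet, as implemented in scanpy 1.11.5, was run on each library with an expected doublet rate of 0.06, and called 11 young cells (0.415%) and 10 aged cells (0.394%), which were removed. So few calls mean that doublets were largely not detected, and clusters of high depth may hold some. This left 2639 young cells (51.2% of barcodes) and 2527 aged cells (53.4%). The 10% limit removed cells unevenly, since the astrocyte or quiescent stem cell-like cluster found at a limit of 20% had more mitochondrial UMIs than the other cells, and a limit of 20%, which keeps 4117 and 3937 cells, was added as an alternative.

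UMIs were summed over the kept cells of each library and given as CPM. Genes with at least 10 CPM in either library were compared by the log2 ratio of CPM plus 1. Sums have exact Poisson intervals, ratios exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and for counting error only. Counts of genes at least 2-fold apart follow a rule of size, and no test or p-value was computed, because each group has 1 library. For each of 43 gene lists and 16 lists of cell type markers, the median log2 ratio of the compared members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, where at least 3 members were compared. A list was called low or high below the percentile 2.5 or above 97.5. Simulated libraries of 8219 genes were drawn as Poisson counts with the real means and depths, so they hold counting error only. In them 100% of genes changed 3-fold and 0% of those changed 1.5-fold passed the 2-fold rule. There 0 unchanged genes did so, and 95.2% of the intervals held the true ratio. On simulated libraries 3% of unchanged lists fell outside the middle 95%, and 100% of lists of 20 genes raised 1.2-fold on the real libraries lay above the percentile 97.5. These checks do not show how often separate cultures of the same age would pass the rules.

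The genes named are, for all cells and for the main class, the 12 highest and the 12 lowest by log2 ratio among genes with at least 50 CPM in either library, leaving out mitochondrially encoded genes, ribosomal protein genes, pseudogenes and gene models named Gm or Rik. Up to 4 members of each list with the largest ratio either way were named too, as were Sox2, Nes, Gfap, Egfr, Mki67, Dcx, Olig2, Cdkn1a, Cdkn2a, Xist and Ddx3y whatever their value. A few genes that these rules pick are not reported here. Gm47283, mt-Nd3, Nnt, Trib3, Nupr1, Chac1, further list members and the genes that mark clusters fall outside this rule, and were named after their values were seen.

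Cells of both libraries were clustered together on log-normalized counts, 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1, with no integration, which gave 13 clusters. Variable genes and components were computed with numpy, neighbours with scikit-learn, and the graph of shared neighbours was split with leidenalg. A cluster was named after a cell type when at least 3 of the markers fixed for that type were at 10 CPM or more and 1.5-fold above the other cells, more than for any other type, at least 1 of them was among its 10 leading genes, no other type had more markers among those 10, and its median depth in either library was at least 1/3 of that library's. The markers were fixed beforehand, but this rule was not. Its first version asked for no own marker among the leading genes, and that condition was added after the clusters had been seen. It decides which class is the main one, since without it clusters 1, 5 and 6 are cycling-like and form the largest class, cluster 3 is oligodendrocyte precursor-like and cluster 13 mature neuron-like, and that version is among the alternatives. The rule kept clusters 1, 6 and 11, whose most frequent markers were those of cycling cells, out of the cycling-like class, and they hold 11.5%, 8.68% and 6.03% of young and 11.9%, 8.31% and 3.92% of aged cells. Cluster 8, nearest to the astrocyte or quiescent stem cell-like class with only 2 of its markers, holds 8.79% and 6.33%, cluster 3 holds 8.56% and 11.6%, and cluster 13 holds 2.20% and 5.14%. Clusters 10 and 12 had median depths of 2268 and 3415 UMIs and were left unnamed for low depth, with 6.10% and 3.98% of young and 5.38% and 3.56% of aged cells. Where an alternative let in barcodes outside the filter without a new clustering, each was given the most frequent cluster among its 20 nearest kept cells. This places every such barcode in 1 of the 13 clusters, whether or not it resembles them. For shares of cells with a UMI and for cell cycle phases, which were scored with scanpy on the S and G2/M lists, each cell was thinned to 5000 UMIs.

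The cell filter, the size rules, the gene lists, the markers, the rule for named genes and most alternatives were chosen before the data were examined. The alternatives were no cell filter, a stricter filter, doublets kept, TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 in R 4.3.3, totals without mitochondrial and ribosomal protein genes, cells weighing the same, thinned cells, CPM minimums of 1 and 50, a pseudocount of 5, equal class shares, G1 cells only and other clusterings. Those added after seeing the data are the 20% mitochondrial limit, leaving out low-depth clusters, equal shares of all clusters, clustering without genes 1.5-fold apart, the looser names and equal weight of the class's clusters. The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and leidenalg 0.10.2.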

Results

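Single-cell RNA sequencing libraries were made from primary neural stem cells of the subventricular zone (SVZ), the germinal layer that lines the lateral ventricles of the adult mouse brain. Cells of C57BL/6 mice aged 2 months (young) and 15 to 18 months (aged) were dissociated and kept in proliferation medium before loading, so the values describe cultured cells. Each age is represented by 1 library made from the pooled tissue of 5 mice, and the counts are unique molecular identifiers (UMIs), that is, distinct captured transcripts. The young library held 97774963 UMIs, with a median of 20728 per barcode, and the aged library 101666604 UMIs, with a median of 22697. The lower quartile was 4374 UMIs per barcode in the young and 11859.5 in the aged library, so the libraries differed in their shallow barcodes. After filtering, 2639 young cells with 58891207 UMIs and 2527 aged cells with 60140272 UMIs were compared. The median kept cell had 22951 UMIs and 5126 detected genes in the young library, and 23745 UMIs and 5232 genes in the aged library. Mitochondrially encoded genes took 8.04% of the kept UMIs in the young library and 8.02% in the aged library, and ribosomal protein genes took 15.0% and 15.1%. There were no replicates, so a difference by age cannot be told apart from a difference between 2 cultures or 2 libraries. Sizes below are descriptions of these libraries, and all intervals are 95% intervals that cover counting error only.

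The series concerns transcriptional dysregulation and the activation of neural stem cells in ageing, and the first comparison asked which transcripts differed in abundance between the libraries. Securin (Pttg1), which restrains the separation of sister chromatids, was 4.04-fold lower in the aged library (interval 3.82 to 4.27), at 26.3 counts per 1000000 UMIs (CPM) against 106 CPM. The calcium-dependent phospholipid-binding protein annexin A3 (Anxa3) was 3.75-fold lower (3.55 to 3.96), at 27.5 against 103 CPM. Cdkn2a, which encodes the INK4a inhibitor of cyclin-dependent kinases and the ARF regulator of p53, was 1.85-fold lower (1.79 to 1.91), at 92.7 against 171 CPM, and 3′ counts do not separate its transcripts. In the other direction, the endosomal protein gene Wdfy1 was 5.73-fold higher in the aged library (5.25 to 6.26), at 57.5 against 10.0 CPM, and the transcription factor gene Mef2c was 2.43-fold higher (2.33 to 2.55), at 109 against 44.7 CPM. Most transcripts were close between the libraries. Of 8331 genes with at least 10 CPM in either library, 12 were at least 2-fold higher and 18 at least 2-fold lower in the aged library, together 0.360%, and at 1.5-fold the counts were 67 and 63.

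Among the 12 named genes lowest in the aged library, Sparc, Chl1, Kitl, Nptx1 and Apln encode surface or secreted proteins. This grouping was made by eye and was not tested. The matricellular glycoprotein gene Sparc stood at 26.1 against 58.5 CPM, the adhesion molecule gene Chl1 at 27.4 against 58.0 CPM, and Kitl, the ligand of the Kit receptor, at 42.1 against 81.9 CPM. Nptx1, a neuronal pentraxin, stood at 39.1 against 68.6 CPM and the peptide hormone gene Apln at 52.9 against 90.0 CPM. The G protein subunit gene Gng11 was at 33.0 against 52.9 CPM and the imprinted gene Peg10 at 57.5 against 91.4 CPM. The remaining pair were the immediate early genes Ier3, at 25.4 against 52.7 CPM, and Egr1, at 135 against 246 CPM. Sparc, Chl1, Kitl, Apln, Ier3, Egr1, Pttg1, Anxa3 and Cdkn2a were each lower in 13 of 13 clusters of cells.

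Among the 12 named genes highest in the aged library, Kcnd2, Atp1b2 and Gabra2 encode channel or pump subunits, again a grouping made by eye and not tested. Kcnd2, a voltage-gated potassium channel subunit, stood at 53.2 against 22.2 CPM, 2.40-fold higher. Atp1b2, a subunit of the sodium pump, was at 76.3 against 42.3 CPM, and Gabra2, a subunit of the receptor for the transmitter GABA, at 73.6 against 46.2 CPM. The interferon-inducible gene Ifi27 was at 55.2 against 27.2 CPM, the anchoring protein gene Akap7 at 77.5 against 40.9 CPM, and Nckap5 at 50.1 against 25.6 CPM. Dbx2, a homeodomain transcription factor gene, was at 70.8 against 40.9 CPM. Ramp1, which encodes a subunit of the receptor for calcitonin gene-related peptide, was at 284 against 166 CPM, and the zinc-binding metallothionein gene Mt3 at 246 against 154 CPM. The small GTPase gene Arl4c was at 86.4 against 54.1 CPM. Wdfy1, Mef2c, Kcnd2, Nckap5, Akap7, Atp1b2, Dbx2, Ramp1, Mt3 and Arl4c were higher in 13 of 13 clusters, and Ifi27 and Gabra2 in 12.

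**Figure D1:**
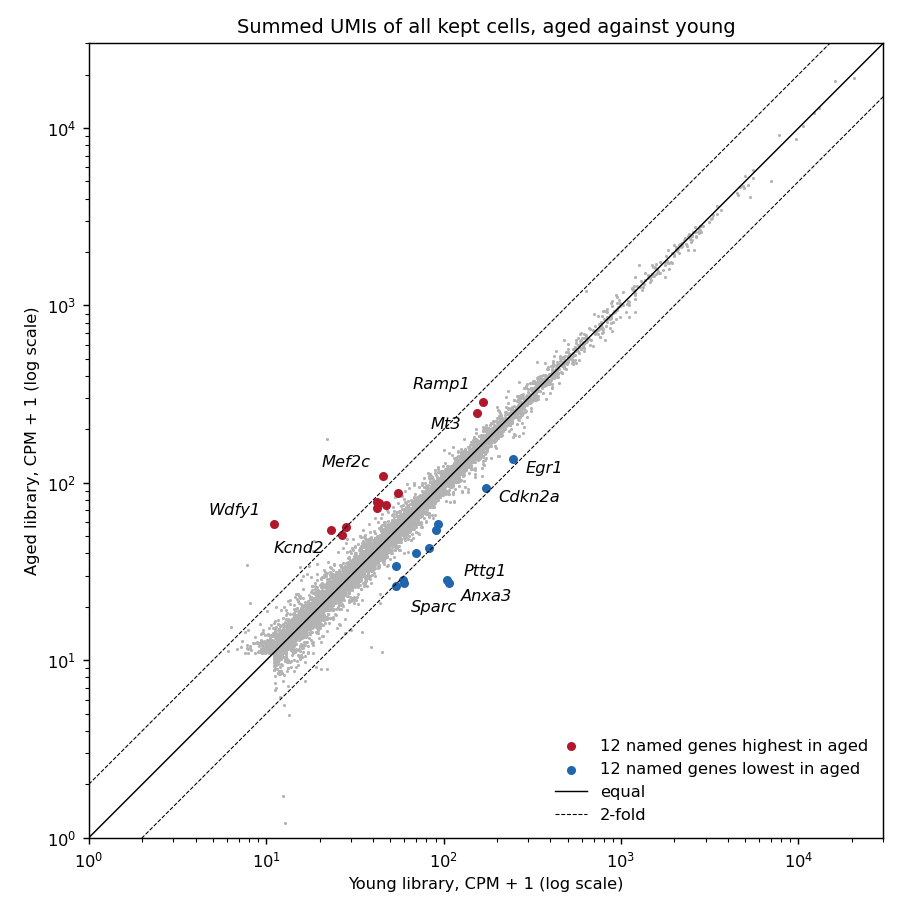
Scatter plot of the UMIs summed over all kept cells, with the young library on the horizontal axis and the aged library on the vertical axis, both as CPM plus a pseudocount of 1 on log scales. Each grey point is 1 of the 8331 genes compared, red and blue points are the 12 named genes highest and the 12 lowest in the aged library, the solid line marks equal values and the dashed lines 2-fold differences; Wdfy1 lies at 10.0 and 57.5 CPM and Pttg1 at 106 and 26.3 CPM.

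Positions of the main genes are given on GRCm38/mm10 with the GENCODE vM21 annotation. Pttg1 (ENSMUSG00000020415) is a protein-coding gene on chromosome 11, from 43420250 to 43426251 on the minus strand. Anxa3 (ENSMUSG00000029484) lies on chromosome 5 from 96793339 to 96845966 on the plus strand. Cdkn2a (ENSMUSG00000044303) lies on chromosome 4 from 89274471 to 89294653 on the minus strand. Wdfy1 (ENSMUSG00000073643) lies on chromosome 1 from 79702262 to 79776143 on the minus strand. Mef2c (ENSMUSG00000005583) lies on chromosome 13 from 83504034 to 83667080 on the plus strand. Egr1 (ENSMUSG00000038418) lies on chromosome 18 from 34859823 to 34864984 on the plus strand. Of the genes that the naming rule leaves out, 2 lay above the 12th highest named gene, and both were picked out after their values were seen. Gm47283 (ENSMUSG00000096768), annotated on chromosome Y from 90784738 to 90816464, stood at 175 CPM in the aged and 20.9 CPM in the young library, 8.40-fold higher (7.92 to 8.92), and counts of a gene with near-identical copies are uncertain. The mitochondrially encoded subunit gene mt-Nd3 stood at 1201 against 634 CPM, 1.89-fold higher (1.87 to 1.92).

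Immediate early genes, the transcription factor and feedback genes that are switched on within minutes of a stimulus, were lower in the aged library as a group. Of 13 members compared, 11 had lower and 2 higher values in the aged library, and 5 were at least 1.5-fold lower. Fosb stood at 3.89 against 12.5 CPM, Fos at 20.1 against 42.6 CPM and Junb at 13.2 against 26.7 CPM. The list median was −0.43 on the log2 scale, lower than all of 10000 random lists of the same size and mean expression. After each cell was thinned to 5000 UMIs, 9.10% of aged and 17.1% of young cells had a Fos UMI, and 39.4% and 58.7% had an Egr1 UMI. DNA damage response and p53 target genes also lay low, with a median of −0.19 (percentile 0) and 14 of 18 members lower in the aged library. Plk2, a p53-responsive kinase gene, was at 88.7 against 125 CPM and the cyclin gene Ccng1 at 126 against 166 CPM. Cdkn1a, a main p53 target that arrests the cell cycle, was at 358 against 388 CPM.

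Of the 43 gene lists, 41 had enough members for a median, and 6 lay below and 4 above the middle 95% of random lists over all cells. Apart from the lists above, the low ones were glycolysis (median −0.09, percentile 0.550), proteasome (−0.06, 0.820), lysosome and autophagy (−0.05, 1.12) and cell cycle S (−0.04, 1.66), all small shifts. Among glycolytic genes, the phosphofructokinase gene Pfkl was at 13.5 against 21.1 CPM, while the aldolase gene Aldoc was at 67.3 against 47.9 CPM. The high lists were metallothioneins (0.32, percentile 99.8), oligodendrocyte lineage (0.21, 99.955), mitochondrially encoded genes (0.09, 98.5) and cholesterol and fatty acid synthesis (0.07, 97.7). The metallothionein list has only 3 members, the fewest allowed, and only Mt3 was at least 1.5-fold higher. Of the 13 mitochondrially encoded genes, 8 were higher and 5 lower, and only mt-Nd3 by 1.5-fold. Together they took 8.02% of aged and 8.04% of young kept UMIs, after cells had been filtered on these same genes. In the cholesterol list, 19 of 26 members were higher in the aged library, among them the synthase genes Hmgcs1, at 635 against 474 CPM, and Lss, at 44.1 against 31.7 CPM. The oligodendrocyte list was split, since Cspg4 (42.0 against 26.2 CPM), Lhfpl3 (82.4 against 52.2 CPM) and the transcription factor gene Nkx2-2 (32.6 against 25.4 CPM) were higher and the transcription factor genes Olig1 (861 against 1109 CPM) and Olig2 (470 against 538 CPM) lower, and its median was −0.20 when only genes with at least 50 CPM were taken. Of the 31 lists in the middle, oxidative phosphorylation had a median of 0.04 (percentile 94.8), hypoxia response −0.08 (2.565), Notch signalling −0.06 (4.32), interferon response 0.14 (93.9) and ribosome biogenesis −0.03 (10.1).

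Lists of the transcription machinery, to which the series title points, were nearly level between the libraries over all cells. RNA polymerase II and the general transcription factors had a median of −0.01 over 34 members (percentile 22.9), and no member was 1.5-fold apart. Elongation factors and Mediator had a median of 0.02 (percentile 60.6), splicing factors 0.01 (58.0), chromatin remodellers and histone modifiers 0.04 (87.2) and DNA methylation 0.04 (71.4). Among the stem cell genes followed whatever their value, the growth factor receptor gene Egfr was at 166 against 144 CPM, 1.15-fold higher in the aged library (1.12 to 1.19). The progenitor genes Sox2 and Nes were at 288 against 262 CPM and 638 against 675 CPM. The list of activated stem cell genes had a median of −0.03 (percentile 11.2) and that of quiescent stem cell genes 0.02 (percentile 63.7). Gfap, the astrocyte filament gene, had only 21 aged and 26 young UMIs, and the neuroblast gene Dcx 131 and 68 UMIs. Xist, expressed from the inactive X chromosome, had 14 aged and 2 young UMIs, a ratio of 6.85 (1.57 to 62.1), and the Y-linked gene Ddx3y was at 41.6 against 35.7 CPM.

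**Figure D2:**
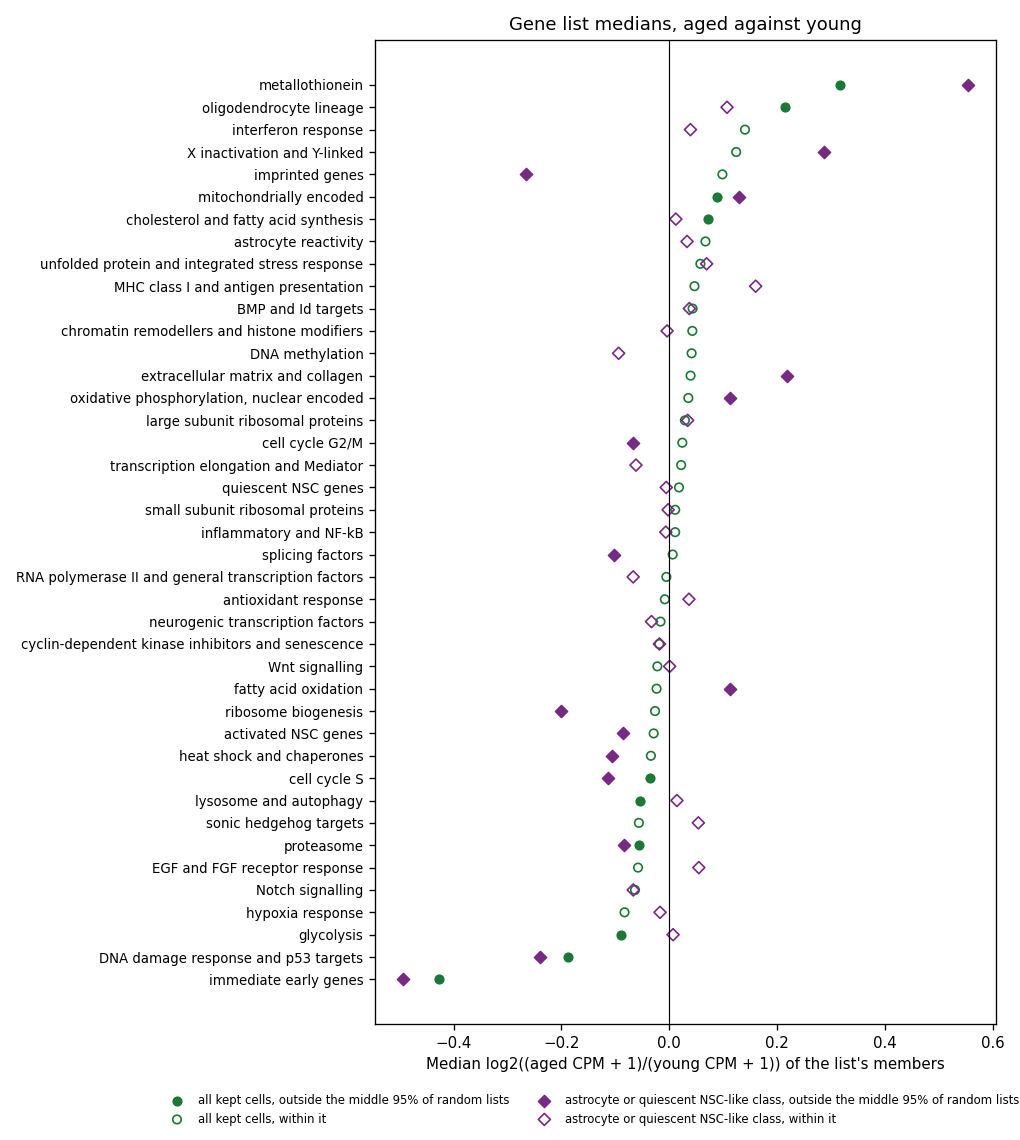
Median log2 ratio of the aged to the young library (CPM plus 1) for the 41 gene lists with at least 3 members compared, on the horizontal axis, ordered by the value over all kept cells. Circles are all kept cells and diamonds the astrocyte or quiescent stem cell (NSC)-like class, and filled symbols lie outside the middle 95% of 10000 random lists. Immediate early genes lie lowest at −0.43 and −0.49, and metallothioneins, a list of only 3 members, highest at 0.32 and 0.55.

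The second comparison was made within the named class with the most cells, clusters 7 and 9. Of the 18 astrocyte or quiescent stem cell markers, 8 were raised in cluster 7. Only 3, the fewest that the naming rule allows, were raised in cluster 9. After thinning, 61.5% of the cells of cluster 9 had an Mki67 UMI in both libraries. The class name therefore does not mean that its cells were quiescent. In this class Trf, which encodes the iron carrier transferrin, was lower in the aged library, at 22.9 against 54.2 CPM. Gmpr, a guanosine monophosphate reductase gene, was 3.81-fold higher in the aged library (3.22 to 4.53), at 71.2 against 18.7 CPM, and the histone deacetylase gene Hdac5 3.29-fold higher (2.74 to 3.97), at 54.1 against 16.4 CPM. Of 8248 genes compared, 47 were at least 2-fold higher and 20 at least 2-fold lower in the aged cells of the class. The class held 448 young cells with 9914721 UMIs and 325 aged cells with 7629305 UMIs. Cluster 9 held most of its young cells (233 of 448) and cluster 7 most of its aged cells (189 of 325). Anxa3 and the mitochondrial protein gene Chchd10 were themselves among the 10 leading genes of cluster 7. The excess of higher genes was not seen with up to 20% of mitochondrial UMIs allowed per cell, where 34 genes were higher and 37 lower.

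Many genes that stood apart over all cells did so inside the class. At least 2-fold apart in both were 24 genes, although the cells of the class are part of all cells and these sets are not independent. Wdfy1 stood at 63.2 against 12.1 CPM, Mef2c at 136 against 50.5 CPM, Nckap5 at 64.4 against 23.5 CPM, Akap7 at 72.1 against 31.5 CPM and Ifi27 at 58.3 against 26.8 CPM. The kinase gene Grk3, which desensitises G protein-coupled receptors, was at 67.2 against 25.5 CPM, Chchd10 at 87.0 against 40.2 CPM, the monoglyceride lipase gene Mgll at 50.5 against 23.4 CPM, and Hbegf, a ligand of the Egfr receptor, at 95.03 against 44.9 CPM. The lowest genes included Pttg1 at 53.2 against 132 CPM, Anxa3 at 93.5 against 228 CPM, Apln at 84.8 against 164 CPM, Peg10 at 92.8 against 167 CPM, Cdkn2a at 105 against 187 CPM and Egr1 at 105 against 201 CPM. Sparc (48.4 against 95.1 CPM), Chl1 (29.6 against 58.5 CPM), Nptx1 (84.5 against 144 CPM) and Ier3 (33.7 against 56.7 CPM) were also among the 12 lowest.

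Oxidative phosphorylation genes were higher and ribosome biogenesis genes lower in the aged cells of the class, by small amounts. Over all cells the medians of these lists were 0.04 and −0.03, both within the middle 95%. Cluster 7 weighs more in the aged cells of the class, so the mix of clusters 7 and 9 may add to the class values. Cell cycle genes lay low over the class as a whole but not with clusters 7 and 9 weighing the same, where the median of cell cycle G2/M was 0.06 and that of cell cycle S −0.01. Nuclear-encoded oxidative phosphorylation genes had a median of 0.11, above all random lists, with 39 of 44 members higher in the aged library, among them the cytochrome oxidase subunit genes Cox7c (1128 against 889 CPM) and Cox6c (794 against 627 CPM). Mitochondrially encoded genes, on which the cells had been filtered, had a median of 0.13 (percentile 99.25), with 11 of 13 members higher but only 1 by 1.5-fold. Fatty acid oxidation had a median of 0.11 (98.0). Metallothioneins, a list of only 3 members, had 0.55 (99.97), with Mt3 at 462 against 225 CPM. The X- and Y-linked list, of which 4 members were compared, had a median of 0.29 (98.35). Ribosome biogenesis genes had a median of −0.20 (percentile 0), with 21 of 25 members lower and none by 1.5-fold, such as the fibrillarin gene Fbl at 203 against 249 CPM. Splicing factors (−0.10, percentile 0.140), cell cycle S (−0.11, 0.0800), cell cycle G2/M (−0.07, 2.315), activated stem cell genes (−0.09, 1.62), heat shock and chaperones (−0.11, 0.970) and proteasome (−0.08, 1.34) also lay low. Immediate early genes (−0.49, 10 of 12 members lower), DNA damage and p53 targets (−0.24, 14 of 17 lower) and imprinted genes (−0.27, 6 of 9 lower) completed the 10 low lists, against 6 high ones. With both clusters weighing the same, 6 lists lay low, and cell cycle S, cell cycle G2/M, activated stem cell genes and splicing factors were not among them. RNA polymerase II and the general transcription factors had a median of −0.07 (percentile 4.36) and elongation factors and Mediator of −0.06 (6.50), both within the middle 95%.

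The extracellular matrix list had a median of 0.22 in the class (percentile 99.92), with Col4a1 at 17.3 against 11.5 CPM and Sparc lower. This direction did not hold over the alternatives, since the median was −0.05 with no cell filter and −0.04 at a mitochondrial limit of 20%. The astrocyte and quiescent stem cell markers had a median of 0.22 (percentile 99.97) over 10 members, of which 5 were higher and 5 lower. The glutamate transporter gene Slc1a3 was at 679 against 382 CPM, 1.78-fold higher in the aged cells (1.71 to 1.86), the cystatin gene Cst3 at 885 against 512 CPM and Aldoc at 102 against 56.7 CPM. Of these markers, 8 were raised in cluster 7 and 3 in cluster 9. Cluster 7 held 189 of 325 aged but 215 of 448 young cells of the class, so the mix of clusters may add to these values. With totals that leave out mitochondrial and ribosomal protein genes the median of the markers was −0.00, and with every cell weighing the same it was −0.08. Over all cells the same markers had a median of −0.10 (percentile 1), which was 0.21 when the named classes were given the same shares in both libraries and 0.00554 when all clusters were.

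The third comparison asked how the cells of each library were made up. Cells of the astrocyte or quiescent stem cell-like class formed 18.2% of the young library (exact Clopper-Pearson interval 16.7 to 19.7) and 13.5% of the aged library (12.2 to 14.9). Cycling-like cells, marked by mitotic genes such as Prc1, Cenpf and Nusap1, formed 8.03% (7.02 to 9.14) and 9.93% (8.79 to 11.2). A cluster whose leading genes included Nupr1, Trib3 and Ddit3, genes of the integrated stress response to amino acid or protein-folding stress, held 2.27% of young cells (1.74 to 2.92) and 5.18% of aged cells (4.35 to 6.12). These shares come from a clustering without the 130 genes that were at least 1.5-fold apart between the libraries over all cells. This was done because leading genes of clusters differed by library, with 5 of 10 in cluster 7 and 2 of 10 in cluster 9 at least 1.5-fold apart within the cluster, and not all of these are among the 130. With the 130 genes kept, the 3 shares were 17.0%, 7.73% and 2.20% in the young library and 12.9%, 9.85% and 5.14% in the aged library. There the cycling-like class was cluster 5 alone. Of the clusters that the naming rule left out, cluster 1, with 3 cycling markers raised, held 11.5% of young and 11.9% of aged cells. Clusters 6 and 11, with 11 and 12, held 8.68% and 6.03% of young and 8.31% and 3.92% of aged cells. No higher share of cycling cells in the aged library is therefore read from the class. At a mitochondrial limit of 20% the astrocyte or quiescent stem cell-like shares were 26.5% in the young and 23.8% in the aged library. In these shares each added cell was placed in the most frequent cluster among its nearest kept cells. When all cells within the 20% limit were clustered again, the cluster of that name held 14.1% and 13.6%. These were largely other cells, since only 191 of its 1119 cells were among those kept at 10%, and its Mki67 level was 15.2 CPM. When each library was clustered alone, the cluster with the highest Trib3 level held 10.8% of young and 5.14% of aged cells, and in the young library it also held Mxd4 and Gng3 among its leading genes.

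**Figure D3:**
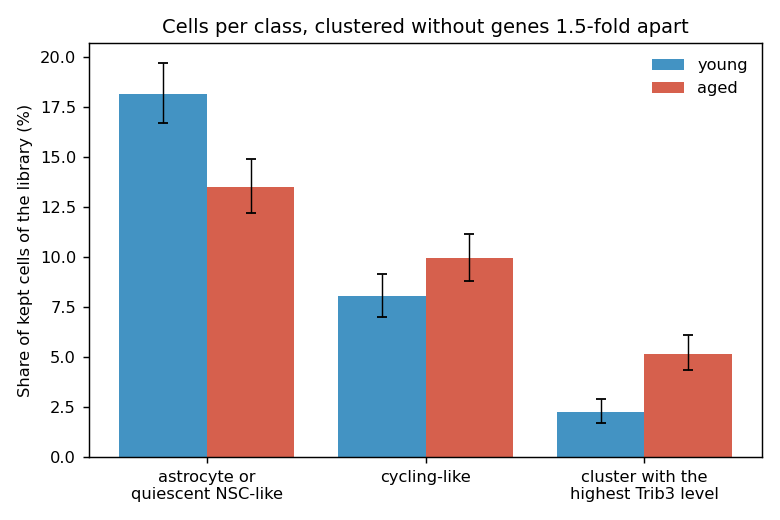
Bars give the percent of kept cells in the astrocyte or quiescent NSC-like class, the cycling-like class and the cluster with the highest Trib3 level, for 2639 young (blue) and 2527 aged (red) cells, clustered without genes 1.5-fold apart; error bars are exact 95% binomial counting intervals. The bars stand at 18.2% and 13.5%, 8.03% and 9.93%, and 2.27% and 5.18%. The cycling-like class leaves out other clusters whose most frequent markers were those of cycling cells.

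Oligodendrocyte precursor markers such as Olig1 and Olig2 were abundant, and a class named after them appeared in other clusterings. It held 23.9% of young and 27.1% of aged cells at Leiden resolution 0.5, 21.0% and 23.5% when cell cycle genes were left out of the clustering, and 8.57% and 8.97% at a mitochondrial limit of 20% with the cells clustered again. Markers of vascular, immune, ependymal and choroid plexus cells were scarce. Of 16 marker lists, 5 had 3 or more members at 10 CPM, namely astrocyte or quiescent stem cell, activated stem cell (median 0.04, percentile 70.7), cycling (0.06, 94.97), neuroblast (0.05, 63.1) and oligodendrocyte precursor (0.09, 87.5). The endothelial genes Pecam1 and Kdr were at most 0.679 CPM, and the T cell gene Cd3e was at 0 in both libraries. The microglial gene Tyrobp was at 0 in the aged and 0.017 CPM in the young library. No border macrophage, ependymal, choroid plexus or erythroid marker reached 10 CPM, the ependymal factor gene Foxj1 being at 3.44 against 4.21 CPM.

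The fourth comparison asked whether the share of dividing cells differed. Mki67, a protein of proliferating nuclei, was at 582 CPM in the aged and 578 CPM in the young library, a ratio of 1.01 (0.993 to 1.02). After thinning to 5000 UMIs, 63.6% of 2264 aged cells (61.5 to 65.5) and 67.5% of 2296 young cells (65.5 to 69.4) had at least 1 Mki67 UMI, with 263 and 343 shallower cells left out. The CPM were level while the thinned share was lower in the aged library. The gap in shares changed in size with the depth and the UMI minimum, so no order is read from it. Unthinned shares were 78.2% of aged and 80.4% of young cells, and shares with at least 2 UMIs in thinned cells were 49.9% and 50.6%. With at least 1 UMI they were 47.5% and 49.5% after thinning to 2000 UMIs. After thinning to 10000 UMIs they were 73.3% (71.4 to 75.1) and 77.3% (75.5 to 79.0). The cluster with the lowest share was the stress response cluster 13, with 9.38% in the aged and 14.0% in the young library. Cells called S or G2/M made up 71.1% (69.2 to 73.0) of thinned aged cells and 74.4% (72.6 to 76.2) of thinned young cells, and 74.8% and 77.9% of unthinned cells. Free RNA can enter such calls, and they are not read as cycling on their own. Within the astrocyte or quiescent stem cell-like class Mki67 was at 149 against 180 CPM, the thinned shares with Mki67 were 37.2% of 290 aged cells (31.7 to 43.1) and 42.6% of 387 young cells (37.7 to 47.7), and the shares in S or G2/M were 44.8% and 47.5%. Unthinned, the class shares in S or G2/M were 45.8% and 56.2%. With at least 2 Mki67 UMIs in thinned cells the class shares turned, at 22.8% of aged and 21.2% of young cells. With at least 1 UMI they were 19.7% and 27.9% after thinning to 2000 UMIs, and 48.2% and 56.9% after thinning to 10000 UMIs. The class joins clusters that differ in Mki67, whose thinned shares were 61.5% of cells in both libraries in cluster 9, and 16.1% of aged and 17.5% of young cells in cluster 7. The thinned shares in S or G2/M were 82.96% of aged and 73.8% of young cells in cluster 9, and 11.6% and 12.7% in cluster 7. As cluster 7 weighs more in the aged library, no lower proliferation of aged cells is read from the class values.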

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

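The low depth test, the heat shock test, the stress list test and the transcript length test were chosen only after the results they concern were seen, as were the clusterings at a mitochondrial limit of 20%, and the rule for reading the stress list test was changed once its value was known. Cells between 10% and 20% of mitochondrial UMIs were outside the comparisons, and they held a clear cell state. When they were added and the cells clustered again, 928 of the 2890 added cells (32.1%) fell in the astrocyte or quiescent stem cell-like cluster, against 3.70% of the cells kept before. The cluster then held 1119 cells, 582 young and 537 aged. Its cells had a median of 27644 UMIs and a median mitochondrial share of 12.6%, so they were not shallow. The lipid carrier gene Apoe stood at 1005 CPM in this cluster and 156 CPM in all other cells, the water channel gene Aqp4 at 25.2 and 3.09 CPM, and Mki67 at 15.2 and 553 CPM.

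Immediate early genes were lower in the aged library, with a list median of −0.43. Barcodes of low depth are argued against, since the median was −0.34 or lower in each cluster that was not of low depth, and whether damaged cells of normal depth played a part stays open. A different mix of clusters is argued against too, since the median was below −0.2 in 13 of 13 clusters. Handling of the cultures before loading cannot be told apart from age with 1 culture each, and the heat shock list, at −0.034 over members that went both ways, did not decide it. A lower immediate early response of aged cells is a hypothesis that stays open, and it could not be tested here.

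The cluster led by stress response genes was larger in the aged library. The limit on mitochondrial UMIs is argued against as the cause, since the difference was 2.90 percentage points at a limit of 20%, with shares of 2.94% (2.44 to 3.50) in young and 5.84% (5.13 to 6.62) in aged cells. Depth per cell is argued against, since after thinning 2.78% of aged cells (2.14 to 3.55) and 1.44% of young cells (0.991 to 2.01) had a Trib3 UMI, a difference of 1.35 points. A stress response of the whole aged culture stays open, because the integrated stress response list had a median of 0.052 over all other clusters with members from −0.21 to 0.37, and so does age. The cluster was found and tested on the same data, and with each library clustered alone its share was not higher in the aged library.

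Single genes lay far apart between the libraries in all or nearly all clusters. Gm47283, Wdfy1, Pttg1 and Anxa3 were each at least 1.5-fold apart in the same direction in 13 of 13 clusters, and mt-Nd3 in 12. All of them were picked for their ratios over these same cells, so a difference in most clusters was likely from the start. A difference in all clusters is what a variant carried by the mice of 1 pool would give, which may therefore be a source of it. Any difference that acts in all cells, age included, would give it as well, so the pattern over clusters decides nothing. For Pttg1 the log2 ratio ranged from −3.01 to −0.67 over clusters and for mt-Nd3 from 0.43 to 0.96. There 1 cluster was under 1.5-fold within its counting error, so for mt-Nd3 even the pattern over clusters stays undecided. Fuller recovery of short transcripts in the aged library stays open for mt-Nd3. Its log2 ratio of 0.92 lay above 0.67, the value that 2.5% of the 53 compared genes under 600 nucleotides exceeded, but mt-Nd3 is 1 of these genes and was picked for its ratio, so this decides nothing.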

How the results depend on the processing

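No paired analysis was possible because each age has 1 library. The alternatives named as added were chosen after the data were seen, and where no reason is given the cause was not tested. Over all cells, TMM and DESeq2 factors left the counts of genes 2-fold apart at 12 higher and 18 lower. The stricter cell filter kept only 158 cells and moved most values by small counts. With it, 251 genes were higher and 250 lower over all cells, and 2 lists lay above the middle 95%. The medians of cell cycle S (0.000351) and of cholesterol and fatty acid synthesis (−0.0919) and the log2 ratio of Insm1 (1.10) turned direction. A minimum of 50 CPM gave 4 higher and 5 lower of 3425 genes, and a minimum of 1 CPM gave 25 and 35 of 12035. At 10 CPM the counts were 12 and 18 of 8331, so a larger share passed when genes of low CPM were included. A pseudocount of 5 gave 9 lower genes, because it shrinks ratios of low values. The oligodendrocyte lineage median was −0.20 at 50 CPM. With the same class shares 7 lists lay above, and the astrocyte or quiescent NSC markers had a median of 0.21, or 0.00554 with the same shares of all clusters (added).

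In the main class, TMM factors gave 46 higher and 21 lower genes. The stricter filter kept 75 young and 83 aged cells, of which only 13.3% and 7.23% were in the class. Its counts, medians and ratios in the class rest on so few cells that no change of direction is read from them. The counts of higher and lower genes were 1685 and 3454 with the stricter filter, 112 and 83 in thinned cells, 17 and 4 at 50 CPM, 119 and 62 at 1 CPM and 21 and 11 with a pseudocount of 5. Lower genes numbered 36 with no filter, 37 with every cell weighing the same, 37 at a mitochondrial limit of 20% (added) and 36 in G1 cells only. Lists below the middle 95% numbered 4 with the stricter filter, 5 in thinned cells and 6 with the clusters of the class weighing the same (added), and lists above numbered 3 with the stricter filter, 3 with every cell weighing the same and 3 in thinned cells. With the stricter filter these medians turned: proteasome 0.0170, fatty acid oxidation −0.0852, splicing factors 0.18, extracellular matrix −0.65, X- and Y-linked −0.52 and astrocyte or quiescent NSC markers −0.28. So did the log2 ratios of Trf (1.62), Nptx1 (0.23), Ier3 (0.88), Aldoc (−0.22), Nupr1 (−5.45), Hbegf (−1.63), Chchd10 (−1.52), Cspg4 (−0.65) and Grk3 (−0.0840). The extracellular matrix median was −0.0494 with no filter and −0.0383 at a limit of 20% (added). The astrocyte or quiescent NSC markers had −0.00435 with totals without mitochondrial and ribosomal protein genes and −0.0811 with every cell weighing the same. Cell cycle G2/M had 0.0610 with the clusters of the class weighing the same (added).

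The looser class names (added) make the cycling-like clusters the main class, so other cells are compared. There 14 genes were higher, 6 lists lay below, and these values turned: cell cycle G2/M 0.0396, activated NSC genes 0.00873, heat shock 0.0215, fatty acid oxidation −0.0424, ribosome biogenesis 0.0397, splicing factors 0.0239, imprinted genes 0.0531 and Vegfa −0.11.

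The astrocyte or quiescent NSC-like share, aged minus young, was −4.12 points in the main clustering. It was −1.64 with no filter, −6.10 with the stricter filter, −2.11 with each library clustered alone and −0.497 at a limit of 20% with cells clustered again (added), where the cluster of that name held largely other cells. The cycling-like difference was 6.97 points with the stricter filter, which kept 75 young and 83 aged cells. The cluster with the highest Trib3 level had −5.69 points with each library clustered alone, where the young cluster held 286 cells and other leading genes. The Mki67 difference over all cells was −0.742 points with at least 2 UMIs, −0.993 with no filter, 3.80 with the stricter filter and −0.526 at a limit of 20% (added), and in the main class 11.4 with the stricter filter. The S or G2/M difference over all cells was 9.25 points with the stricter filter. These stricter filter shares rest on 63 aged and 53 young thinned cells, and on 5 and 7 in the main class. The Mki67 shares were 69.8% (57.0 to 80.8) and 66.0% (51.7 to 78.5) over all cells, and 40.0% (5.27 to 85.3) and 28.6% (3.67 to 71.0) in the class. Their directions are therefore not read. Leiden resolution 0.5 gave no astrocyte or quiescent NSC-like class, so it has no value for the main class or for that share, and leaving out the cell cycle genes gave none for that share either. In both, an oligodendrocyte precursor-like class, of 1316 and 1149 cells, was the largest named one and would have been the main class.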

Other observations

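The length comparisons and the choice of genes here were made only after the data were seen. Genes with the shortest transcripts were slightly higher in the aged library, and the ratio did not fall steadily with length. By the longest annotated transcript, 53 compared genes under 600 nucleotides had a median log2 ratio of 0.13. The medians were −0.01 for 315 genes from 600 to 1000 nucleotides, −0.04 for 1323 from 1000 to 2000, 0.01 for 3193 from 2000 to 4000 and 0.06 for 3439 above 4000. Inside the ribosomal protein genes, the 43 shorter ones had a median of 0.08 and the 43 longer ones −0.02, with Rps29 at 1698 against 1258 CPM and Rpl38 at 897 against 704 CPM. Among mitochondrially encoded genes, the 6 shorter ones had a median of 0.26 and the 7 longer ones 0.06. Nuclear-encoded oxidative phosphorylation genes hardly differed, with 0.05 for the 22 shorter and 0.03 for the 22 longer ones. No cause was tested for these shifts.

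Some signalling and lineage genes not described above had other levels in the aged library, of which only Hmga2, Spry4 and Nnt were at least 1.5-fold apart. Hmga2, a chromatin protein gene of young and fetal stem cells, was at 13.7 CPM in the aged and 29.0 CPM in the young library. The Notch target genes Hes5 and Hes1 were at 77.1 against 114 CPM and 51.7 against 62.8 CPM, and Notch1 at 87.8 against 112 CPM, but the Notch signalling list as a whole was split, with 7 members higher and 7 lower. The receptor signalling inhibitor genes Spry4 and Dusp6 were at 39.8 against 61.9 CPM and 62.5 against 86.2 CPM, while Etv5 and Fgfr3 were at 104 against 83.2 CPM and 20.5 against 14.0 CPM. The cyclin gene Ccnd2 was at 912 against 1201 CPM. The fatty acid-binding protein gene Fabp7 was at 4093 against 5342 CPM, and the filament gene Vim at 2041 against 2586 CPM. Among imprinted genes, Mest (188 against 249 CPM) and Ndn (55.6 against 73.4 CPM) were lower and Nnat (361 against 293 CPM) higher. Nnt, a mitochondrial transhydrogenase gene that is partly deleted in the C57BL/6J substrain, was at 18.2 against 11.1 CPM, higher in 13 of 13 clusters, and the labels do not give the substrain.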
